A study of Arabidopsis thaliana with 6 samples.

How the data were processed

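Whole *Arabidopsis thaliana* seedlings, 10 days old, were compared after 1 h with mock treatment or with 20 nM purified protease IV, a secreted serine protease of the bacterium *Pseudomonas aeruginosa* PA14. The labels describe growth in liquid medium in multi-well plates, with the medium renewed on day 8. The control samples are called nontreated in their titles and mock control elsewhere in the labels, which do not say whether a buffer was added or the wells were mixed; they are called mock here. Each group held 3 arrays, labelled as biological replicates. The labels do not say how the wells or cultures were divided among them, so p-values measure the spread between these samples, which may be partly technical. RNA from each sample was hybridized to 1 Affymetrix Arabidopsis ATH1 array, which measures each transcript with a set of short probes near its 3-prime end.

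The deposited values are log2 expression values from robust multi-array averaging (RMA) with affy 1.36.1, per the submitters' processing notes. By construction RMA corrects the background of the probe intensities, quantile-normalizes the arrays and summarises each probe set on the log2 scale. Quantile normalization gives all arrays nearly the same distribution, so a change in the total amount of mRNA per seedling cannot be read from these values. Settings of RMA are not given in the sources used here, and the scanner images and probe-level files were not used here. Signals near background are compressed, so differences of dim genes are understated.

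The table held 22810 probe sets, of which 64 were controls. GEO's platform annotation, which can be old, named exactly 1 gene for 13513 probe sets and several genes for 503, and 8730 probe sets were unnamed. Of the single-gene probe sets, 13436 were matched to NCBI RefSeq (TAIR10.1), which gave current symbols, and 77 kept the name in the annotation. One probe set per gene was used, and 147 genes had more than 1 single-gene probe set, for which the set with the highest mean over all arrays was taken. In 1 of these genes the probe sets disagreed in direction. This left 13355 genes. RefSeq coordinates were used only for which genes neighbour each other and for the span of each gene. Many well-studied immune genes had no single-gene probe set named for them and were not analysed here by name.

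Differences were fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a variance trend), as protease IV minus mock with all 6 arrays and no covariates. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 13355 genes, and the threshold was an adjusted p under 0.05. A stricter count also required a difference of at least 2-fold. All standard errors come from this fit, and SDs are over the 3 arrays of a group. The number of arrays limits the precision. The comparison, the tests, the alternatives and 39 gene lists were fixed before the data were examined, from general knowledge of plant immunity and seedling physiology. Lists were matched through symbols and synonyms, and organellar genes by their genome in RefSeq, where the measured members were all plastid genes. Members are called measured where a single-gene probe set was named for them. Other members may have unnamed probe sets on the array, so counts of measured members do not describe a whole list or family. The 14 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists; 25 lists had fewer, 5 of them none, and their members are given singly.

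Genes named in the text follow a rule with 3 parts. The first took the 15 largest rises and 10 largest falls past the threshold whose groups did not overlap and whose higher group mean was at least 5 on the log2 scale. The second took up to 3 members of each list past the threshold with the largest differences. The remaining part listed immune marker and reference genes whatever their result, such as FRK1, WRKY33 and MPK3, but none of them was measured by a named single-gene probe set, so they are not analysed here. The rule named 78 distinct genes. Other list members are named where a count calls for it, and were chosen after their values were seen.

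RNA quality was read from the 3-prime and 5-prime control probe sets of actin, GAPDH and ubiquitin, and hybridization from 18 probe sets of bacterial controls. Single values per array were compared with two-sided exact permutation tests over the 20 relabellings of the arrays, whose smallest p is 0.1. The alternatives covered the replicate number as a block, each array left out, filters on dim genes, other scalings between arrays, other choices of probe set, other variance models and, for the lists, camera with an estimated correlation, camera on ranks and fry. Added after seeing the data were arrays centred on the bacterial controls, families built from gene symbols, neighbouring genes without probe sets that can match several transcripts, and gene spans matched on the mock mean.

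The fit was tested on simulated arrays with the real means and spreads of all 13355 genes and 200 genes changed. It recovered 80% of genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 8 false calls. The list test called 0 simulated lists when no list was shifted and recovered a list that was. The noise was drawn once and independently for each gene, so this does not test false calls among lists whose members vary together. Permutations, families and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.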

Results

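Transcript levels were measured on 6 arrays, 3 from mock-treated and 3 from protease IV-treated 10-day-old *Arabidopsis* seedlings, harvested 1 h after the protease was added at 20 nM. The array medians lay between 6.08 and 6.13 on the log2 scale. Across genes, the correlation between arrays of 1 group was 0.996 to 0.998, and between groups it was 0.953 to 0.963, although genes are not independent replicates. The first principal component held 91% of the variance. No arrays held identical values.

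The comparison asks which transcripts change in seedlings within 1 h of contact with the bacterial protease. The largest measured rise was in AT1G26380, which encodes a berberine bridge enzyme-like oxidase. Its level went from 3.81 ± 0.083 in mock to 12.36 ± 0.074 in protease IV-treated seedlings (SD, n = 3 each), a difference of 8.56 on the log2 scale or 377-fold (limma, adjusted p = 1.05e-12). That mock level lies below the lower quartile of every array (3.98 to 4.05), where signals are compressed, so the fold is that of the measured values. AT1G26410 and AT1G30700 of the same enzyme family rose by 5.80 and 6.42. Genes of early immune signalling rose with them, among them the ubiquitin ligases PUB22, PUB23 and PUB24, which act as brakes on immune signalling, and the transcription factors WRKY22 and WRKY53. The largest fall, in AT3G19850 of the NPH3 family, was 8.27-fold.

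In all, 4564 of 13355 genes passed the threshold in limma, 1525 higher and 3039 lower, so that 66.6% of the calls were lower. This split depended on the scaling: with cyclic loess between the arrays 2060 genes were higher and 1514 lower, and 42.4% of the calls were lower. Large changes were mostly rises. Of the 758 genes that also changed at least 2-fold, 602 were higher and 156 lower. A rise of at least 8-fold was seen in 142 genes and of at least 32-fold in 28, whereas 8 genes fell at least 4-fold. The values of the groups did not overlap in 6093 genes, or 45.6% of those tested, against 10% by chance. In 174 of the 602 rising genes the mock mean was under 5 on the log2 scale, which is dim for these arrays. That is 28.9% of the rising genes, against 43.3% of all genes tested.

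**Figure D1:**
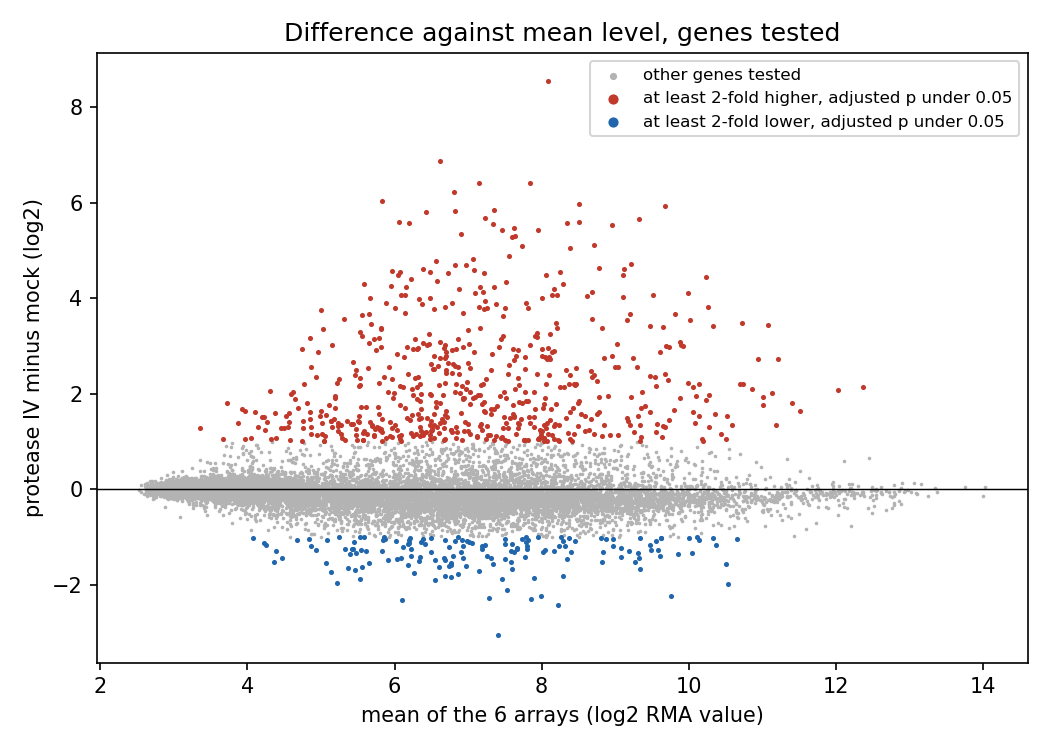
Protease IV minus mock difference of each gene (log2) against its mean over the 6 arrays (log2 RMA value), with 1 point per gene. The 602 genes at least 2-fold higher with an adjusted p under 0.05 are in red and reach 8.56, the 156 at least 2-fold lower are in blue and reach -3.05, and other genes are grey.

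The 15 largest rises ranged from 5.60 to 8.56, and 8 of them had a mock mean below the lowest lower quartile of the arrays, so their order is that of measured values near background. After AT1G26380 came AT3G01830, which encodes a calmodulin-like calcium-binding protein and rose by 6.87 (SE 0.083). AT3G12910, a NAC-family transcription factor, went from 2.81 ± 0.085 to 8.84 ± 0.24 (SD, n = 3 each). AT1G66090, which encodes a TIR-NBS protein of the disease resistance type, rose by 5.83. AT5G39580, a secreted peroxidase of the class that acts at the cell wall, rose by 5.65, and AT1G02360, of the chitinase family, by 5.60. AT1G65690, of the NDR1/HIN1-like family, rose by 5.86. Also in this group were AT3G54150 at 6.41, AT3G02840, which encodes an ARM-repeat protein, at 6.23, AT2G44370, with a cysteine- and histidine-rich C1 domain, at 5.97, AT1G19020 at 5.94, AT1G56060 at 5.68 and AT5G52760 at 5.61. Adjusted p-values in limma were at or below 9.36e-10 for these 15 genes.

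The 10 largest falls ranged from -1.97 to -3.05. AT3G19850 went from 8.93 ± 0.066 to 5.89 ± 0.33 (SD, n = 3 each; limma, adjusted p = 4.44e-08). AT3G28270 fell by 2.42, AT5G20790 fell by 2.31 and AT5G03230 fell by 2.30. AT3G16560, which encodes a type 2C protein phosphatase, fell by 2.27, and AT4G33666 fell by 2.23. AT5G47610, with a RING domain, fell by 2.23. AT5G26200, a mitochondrial carrier family member, went from 8.59 ± 0.17 to 6.48 ± 0.29 (SD, n = 3 each). AT2G41250, of the haloacid dehalogenase-like hydrolases, fell by 1.98 and AT3G15310 fell by 1.97.

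**Figure D2:**
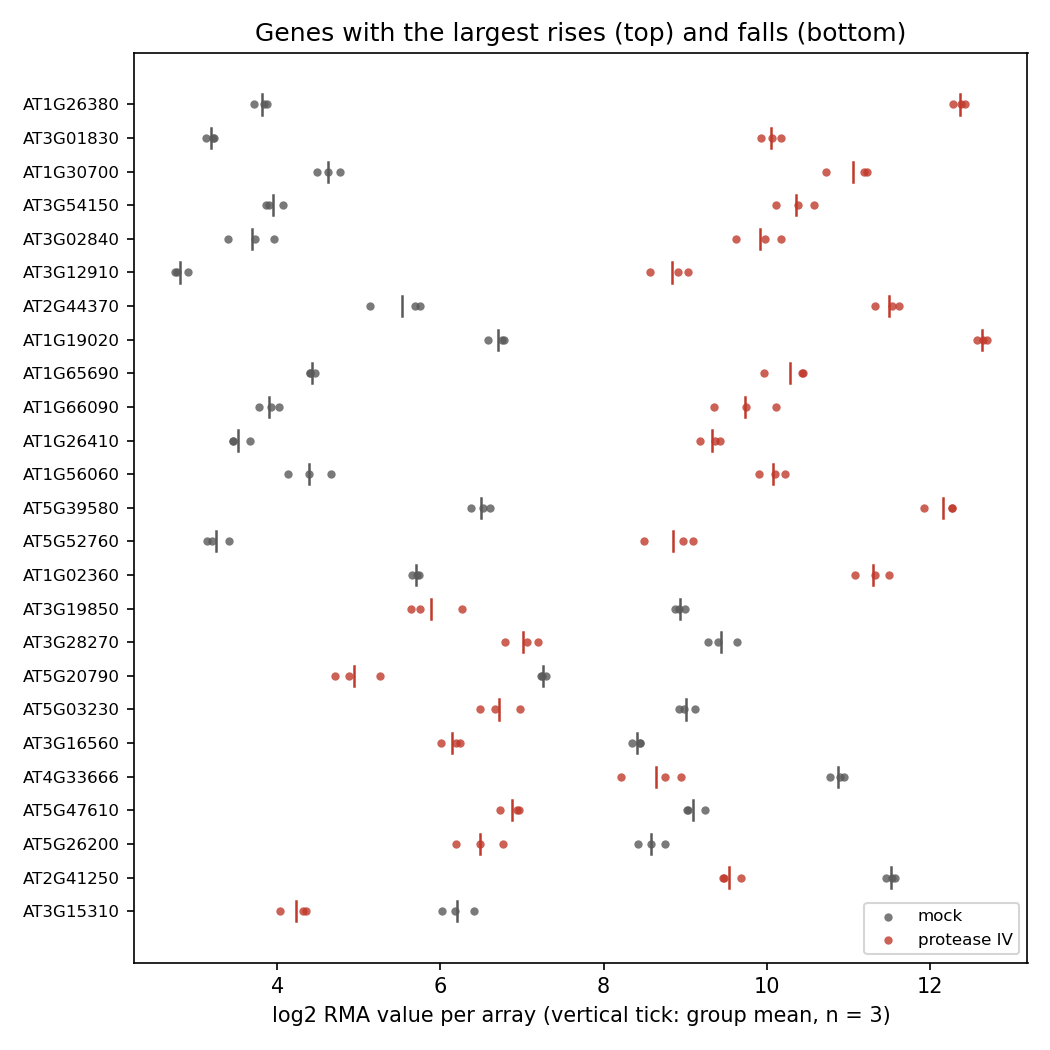
Log2 RMA values on each array for the 15 genes with the largest rises and the 10 with the largest falls, with mock in grey, protease IV in red and vertical ticks at group means (n = 3). In every gene shown the groups do not overlap; AT1G26380 moves from 3.81 to 12.36 and AT3G19850 from 8.93 to 5.89.

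Of the 22 genes in the early immune marker list 6 were measured, and all 6 rose at least 2-fold, with a median difference of 3.92. PUB23 rose by 5.05 (SE 0.11), PUB24 by 4.37 and PUB22 by 4.06. WRKY53 rose by 3.78, WRKY22 by 3.37, and BIK1, a cytoplasmic kinase that carries signals from immune receptors, by 1.61. The list differed from other genes in limma's camera (adjusted p = 2.93e-11, and adjusted p = 0.103 with an estimated correlation of 0.589). All 6 also passed when adjusted over the list alone. WRKY22, WRKY53 and BIK1 are also members of lists described next.

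The list of WRKY transcription factors, a family that regulates defence and senescence genes, held 72 genes, of which only 7 were measured. Of these 7, 4 rose, 2 fell and 1 did not pass. WRKY6 went from 5.97 ± 0.37 to 10.53 ± 0.19 (SD, n = 3 each) and WRKY47 rose by 1.63. ZAP1 fell by 0.42 and WRKY20 fell by 0.34, but neither passed after cyclic loess, where 0 members fell. The camera test in limma gave an adjusted p = 0.00444, adjusted p = 0.103 with an estimated correlation of -0.0502 and adjusted p = 0.375 on ranks. Adjusted over the list alone the counts were again 4 and 2.

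Of 10 measured calcium-binding and calcium-signalling genes, from a list of 34, 7 rose and 1 fell, over all genes and adjusted over the list alone. The calmodulin-like gene AT3G01830, among the largest rises, was not matched to this list. CML42, a calmodulin-like protein, rose by 4.72 (SE 0.12), CML37 by 1.81, CML38 by 1.22 and the glutamate receptor-like channel GLR2.7 by 1.49. The mock mean of CML37, 2.82, lies below the lower quartile of the arrays, so its difference is measured against background and is not exact. GLR3.3, of the same channel family, fell by 0.62. The list passed in limma's camera with adjusted p = 0.000699, and adjusted p = 0.103 with an estimated correlation of -0.0895.

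Among 5 measured pattern recognition receptors and partners, from a list of 31, 4 rose over all genes and 5 when adjusted over the list alone. EFR, the receptor of bacterial elongation factor Tu, rose by 1.53 (SE 0.10). SD1-29, the receptor kinase that senses bacterial 3-hydroxy fatty acids, rose by 1.38 and FER, a malectin-like receptor kinase, by 0.42. AT5G18610 differed by 0.33 (limma, adjusted p = 0.108). The camera test in limma gave adjusted p = 0.000122, and adjusted p = 0.103 with an estimated correlation of -0.0616.

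Precursors of secreted peptides that act as danger signals, a list of 20 genes, had 5 measured members. Of these 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone. AT4G28460 rose by 2.51, AT4G37290 by 1.53 and AT2G23270 by 1.21, all 3 encoding precursors of small peptides induced by immune elicitors. RALFL34 fell by 0.43. With cyclic loess RALFL33 rose as well. The list passed in limma's camera at adjusted p = 0.00452, but not with an estimated correlation (adjusted p = 0.170) or on ranks (adjusted p = 0.105).

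The organellar list shifted by a median of 0.06 over 69 measured transcripts, all of them plastid-encoded, of which 1, atpI, rose (0.37, limma, adjusted p = 0.0391; its groups overlapped, and it did not pass without any 1 of 5 single arrays) and 0 fell; adjusted over the list alone the counts were 0 and 0. The camera test in limma gave adjusted p = 0.0155, and adjusted p = 0.743 with an estimated correlation. This list lost its call without mock replicate 1 (0.111), mock replicate 3 (0.160) or protease IV replicate 1 (0.247), given as adjusted p in limma's camera, and its median was -0.02 with arrays centred on the bacterial controls, where 0 members passed. With cyclic loess the median was 0.21 and 13 of the 69 rose.

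**Figure D3:**
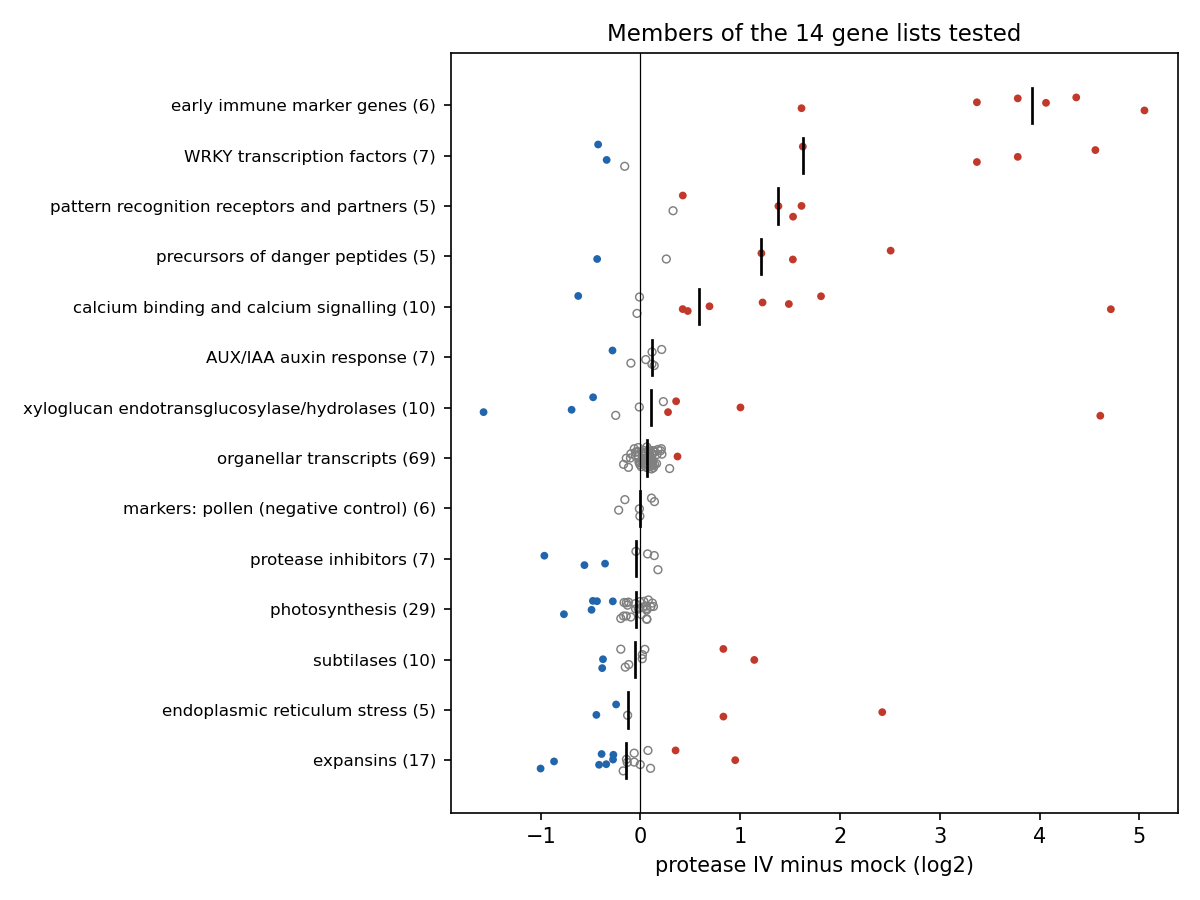
Protease IV minus mock difference (log2) of each measured member of the 14 lists tested, with the number of members in brackets and the list median as a vertical line. Filled points passed an adjusted p under 0.05, red higher and blue lower, and open points did not; the early immune markers lie between 1.61 and 5.05.

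The lists for endoplasmic reticulum stress, xyloglucan enzymes and expansins did not pass in camera and held members that moved in both directions. Among 5 endoplasmic reticulum stress genes, BZIP60 and BZIP28, transcription factors of the unfolded protein response, rose by 2.42 and 0.83. The chaperones CRT1b and ATERDJ3B fell by 0.44 and fell by 0.24 (limma's camera for the list, adjusted p = 0.457), and ATERDJ3B did not pass with cyclic loess. The median of this list was -0.13, whereas its mean was 0.49 and its camera direction was up. Of 10 xyloglucan endotransglucosylase/hydrolases, which remodel cell wall xyloglucan, 4 rose and 3 fell. XTH18 went from 6.81 ± 0.13 to 11.42 ± 0.13 (SD, n = 3 each) and XTH19 rose by 1.00, whereas EXGT-A3 fell by 1.57. The counts were 3 and 3 with median-centred or quantile-normalized arrays, 4 and 2 with cyclic loess, and 2 and 4 with arrays centred on the bacterial controls. Of 17 expansins, which loosen cell walls, 2 rose and 7 fell: EXLA1 rose by 0.95, EXPA16 fell by 1.00 and EXPA15 fell by 0.87. With cyclic loess 2 expansins rose and 3 fell, and with arrays centred on the bacterial controls 1 rose and 7 fell. The camera adjusted p in limma was 0.572 for the xyloglucan enzymes and 0.554 for the expansins. Counts adjusted over the list alone were the same for these 3 lists.

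No measured protease inhibitor rose, and 3 of 7 fell, over all genes and adjusted over the list alone. AT5G47550, of the cystatin family, fell by 0.96, AT2G43530 fell by 0.56 and AT5G05110 fell by 0.36. With cyclic loess SERPIN1 rose, 2 inhibitors fell and AT5G05110 did not pass. The list gave adjusted p = 0.598 in limma's camera. Of 10 subtilases, plant serine proteases, SBT3.3 rose by 1.14 (SE 0.15) and SBT3.5 by 0.83, and S1P, a protease of the secretory pathway, fell by 0.38 together with SBT1.3, which fell by 0.38. With cyclic loess 2 subtilases rose and 1 fell. The remaining 6 did not pass, the counts were the same adjusted over the list alone, and the list gave adjusted p = 0.732 in limma's camera. The median of this list was -0.05, whereas its mean was 0.08 and its camera direction was up.

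Of 29 measured photosynthesis genes 5 fell and 0 rose, or 4 and 0 adjusted over the list alone. All 5 were among the 9 nuclear-encoded members: LHCB4.2, a light-harvesting protein of photosystem II, fell by 0.77, PRK, a Calvin cycle kinase, fell by 0.49 and LHCB4.3 fell by 0.48. None of the 20 plastid-encoded members passed, and their median was 0.03 against -0.28 for the nuclear ones. The split between nuclear and plastid members was made after the values were seen. With cyclic loess the plastid genes psbI and psaB rose and 4 nuclear genes fell, and the list gave adjusted p = 0.593 in limma's camera. Of 7 AUX/IAA auxin response genes, IAA18 fell by 0.29 and 0 rose, with 0 passing when adjusted over the list alone. IAA18 did not pass with cyclic loess. It also did not pass without mock replicate 1, mock replicate 3 or protease IV replicate 1, where its difference was -0.31, -0.22 and -0.25. The AUX/IAA list gave adjusted p = 0.593 in limma's camera. The mock means of IAA29, IAA30, IAA31, IAA33 and IAA34 lay below the lower quartile of the arrays, where signals are compressed.

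Several smaller lists held strongly rising genes. STZ, a zinc finger repressor of stress genes and the only measured member of its list, rose by 4.54. CCR2, a cinnamoyl-CoA reductase of the phenylpropanoid pathway, rose by 4.06, whereas HCT of the same pathway fell by 0.67 and DFR differed by -0.17 (limma, adjusted p = 0.232). SAG101, a partner of EDS1 in salicylate-linked immunity, rose by 2.33, and GRX480, the other measured member of its list, differed by -0.007 (limma, adjusted p = 0.960). Of 4 genes of the reactive oxygen list, the peroxidases AT5G64120 and Prx37 rose by 2.03 and 1.54, and GSTU25 and AT2G21640 did not pass. Of 3 secretion genes KEU, which acts in vesicle fusion, rose by 1.46, and SEC5A and EXO84B did not pass, at 0.14 and 0.003. UGT74B1, of glucosinolate synthesis and the only measured member of its list, rose by 0.62. In the abscisate and drought list, LTI30 rose by 0.50, COR47 fell by 0.27, and COR15A and COR15B did not pass. The cytokinin response regulators RR16 and ARR15 fell by 0.52 and fell by 0.23. Of 3 SAUR auxin response genes AT3G53250 passed in limma with a difference of -0.54, but its group means, 3.72 and 3.17, both lie below the lower quartile of the arrays, so this is a difference between values near background; the other 2 did not pass. With cyclic loess COR47, RR16 and ARR15 did not pass, and COR47 and ARR15 did not pass either without any 1 of 5 single arrays, nor RR16 without mock replicate 2 (limma, adjusted p = 0.052). In limma 0 of 2 measured members passed in the jasmonate, ethylene, AP2/ERF and circadian clock lists. In the cytosolic heat shock list it was 0 of 3. These lists held 30, 23, 22, 23 and 22 genes, most without a named single-gene probe set, so the counts do not describe the pathways. Of the 11 measured genes, EIN3 at 0.17 and AT5G52660 at -0.22 had an unadjusted p under 0.05. EIN3, the AP2/ERF gene tny and SEC5A of the secretion list rose with cyclic loess, and AT5G52660 of the clock list fell with median-centred arrays. No member of the lists for the MAP kinase cascade, heterotrimeric G protein and RACK1, cysteine-rich receptor-like kinases, vascular tissue or embryo and seed was analysed here.

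Markers of cell types and organs were mostly lower or did not pass. Of 4 guard cell and stomatal lineage markers 3 fell: FMA fell by 0.61, SPCH fell by 0.51 and MUTE fell by 0.31, and 4 fell adjusted over the list alone. FMA and SPCH also fell with cyclic loess and MUTE did not pass there. MUTE also did not pass without any 1 of 5 single arrays, and its protease IV mean, 3.83, lies below the lower quartile of the arrays. HPR, a leaf peroxisomal enzyme, fell by 0.39, and the root hair expansin EXPA18 fell by 0.34; neither passed with cyclic loess, and EXPA18 did not pass without 4 of the single arrays. In limma 0 of 2 root markers passed, with PYK10 at -0.17 (unadjusted p = 0.0309), although the root marker AT5G66390 rose with cyclic loess, and the meristem marker CLV3 differed by -0.06 with both group means below the lower quartile of the arrays. The 6 pollen markers, a negative control, gave 0 calls in limma over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.732). Their median was -0.009 and their mean -0.02, whereas the camera direction was up. Both group means of MGH3, AGL104, AGL66 and AtVEX1 among them lay below the lower quartile of the arrays. None of the 4 measured reference genes passed in limma, and 0 had an unadjusted p under 0.05; GAPC2 differed by -0.13 and PEX4 by -0.01, and the median of the 4 was -0.13, or 0.03 with cyclic loess. GAPC2 fell after quantile normalization of the tested genes.

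The actin control had a larger 3-prime minus 5-prime difference in protease IV-treated samples, 1.81 ± 0.28 against 1.58 ± 0.008 in mock (SD, n = 3 each; log2), with no overlap (exact permutation p = 0.1, the smallest the design allows). Protease IV replicate 3 had the highest value, 2.12. For GAPDH and ubiquitin the groups overlapped (exact permutation p = 0.3 and p = 0.8). The means of the bacterial hybridization controls were 9.37 ± 0.10 in mock and 9.45 ± 0.036 in protease IV arrays (exact permutation p = 0.3, n = 3 each). Without protease IV replicate 3, limma called 1446 genes higher and 2501 lower, and 593 and 165 at least 2-fold.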

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

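No test in this part was chosen after its result was seen. Probe sets outside the gene-level comparison also differed between the groups. Among 8730 unnamed probe sets, 538 were at least 2-fold higher and 155 at least 2-fold lower in protease IV-treated seedlings (limma over all probe sets that are not controls). The largest rise among them was 7.54 and the largest fall -2.79; the genes they measure were not named here. Among 503 probe sets that name several genes, 22 were at least 2-fold higher and 2 at least 2-fold lower.

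The ubiquitin control probe sets, used on the array to judge RNA quality, were higher in every protease IV array than in every mock array. The 3-prime set differed by 0.28 (13.16 ± 0.060 against 12.88 ± 0.035, SD, n = 3 each, exact permutation p = 0.1) and the 5-prime set by 0.28. The actin and GAPDH 3-prime sets differed by -0.14 and -0.15, and their 5-prime sets by -0.38 and -0.22.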

How the results depend on the processing

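Centring the arrays on the bacterial controls was chosen after seeing the data. Over all alternatives, 127 of the counts of genes and lists stayed within 1.5 times their values and 5 did not. List medians were counted once per list and alternative, over the alternatives that leave the list test as it was. Of these outcomes 227 kept the call, 3 lost it and 1 reversed. The 78 named genes were counted once per gene and alternative. Of those outcomes 1345 kept the call and 51 lost it, with 0 reversed. With cyclic loess 1514 genes were lower in place of 3039, and 101 in place of 156 at least 2-fold lower. In place of 4564 genes past the threshold, 8577 probe sets passed when every non-control probe set was tested, since more were tested. Of the 6 lists called, 0 passed with an estimated correlation. That estimate was below 0 for the WRKY, calcium and receptor lists, so the loss of their calls cannot be put down to correlation among their members. On ranks 4 of the 6 passed, and the WRKY and danger peptide lists did not. Of the 14 lists tested, 12 passed in fry's mixed test, which asks only whether members change. In fry's directional test the organellar list did not pass (adjusted p = 0.600) and the other called lists did. The endoplasmic reticulum stress (9.74e-05, up), xyloglucan (0.00272, up), expansin (0.00461, down) and protease inhibitor (0.00827, down) lists passed there too. The organellar median of 0.063 reversed to -0.0159 with arrays centred on the bacterial controls. The cause was not tested for these changes, except where stated.

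Leaving out each array in turn gave 3658 to 4705 genes, 731 to 779 at least 2-fold and 5 to 6 lists. Same-numbered arrays did not deviate together (correlations across genes of 0.0379, -0.101 and -0.176), which gives no sign that the numbers pair the samples. Differently numbered arrays gave -0.0604 to 0.159. With deviations from means of 3 arrays, a weak effect of a shared culture cannot be excluded. With the replicate block 4179 genes passed, 1441 higher and 2738 lower, and 758 at least 2-fold. Signal over background limits dim genes: with a mean of at least 5, 4483 of 7644 genes passed, and 4 lists in place of 6, since the receptor and danger peptide lists had too few members left to be tested. In the upper 60% of genes 5 lists passed, since the receptor list had too few.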

Other observations

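The tests by cyclic loess and by centring each array on its median were chosen as tests of the pattern they bear on only after that result was seen, and the families, the neighbouring genes without certain probe sets, the gene spans matched on the mock mean and the centring on the bacterial controls were added after seeing the data. In 41 places neighbouring genes rose together at least 2-fold. In one run of 3, the receptor kinase genes AT1G61360, AT1G61370 and AT1G61380 rose by 4.12, 2.77 and 1.38, and in another AT3G09000, AT3G09010 and AT3G09020 rose by 1.52, 3.09 and 3.04. The pair of berberine bridge enzyme-like genes AT1G26410 and AT1G26420 rose by 5.80 and 5.43, and AT1G51850 and AT1G51860, of the leucine-rich repeat receptor kinases, by 2.87 and 1.81. These genes were chosen after their values were seen.

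Families built from gene symbols, 30 with at least 8 measured members, gave 0 past the threshold by Fisher's exact test among rising genes and 0 among falling ones, with 4 and 1 at an unadjusted p under 0.05. Genes that carry no family symbol in RefSeq were left out, so the counts can miss members. Among those left out was the calmodulin-like gene AT3G01830, which rose by 6.87. The calmodulin-like family CML had 3 of 8 members at least 2-fold higher (adjusted p = 0.0936 by Fisher's exact test), the U-box ligases PUB 3 of 9 (0.0936), the family SEC 3 of 12 (0.148; KEU, SEC15B and SEC1B) and the cytochromes P450 named CYP 4 of 27 (0.236).

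Neighbouring rising genes were more frequent than chance placement gives. Of 5845 measured pairs of neighbouring genes, 43 rose together at least 2-fold, against a mean of 11.8 in permutations, a ratio of 3.64, and 0 of 10000 permutations reached 43 (permutation p = 1e-04, the smallest they can give). Without probe sets whose names mark them as able to match several transcripts the ratio was 3.46, but 599 of the 602 rising genes and 42 pairs were left, so the filter decides little about shared probes. Cross-hybridization between tandem copies stays open, and whether the neighbours are related in sequence was not tested. Among genes at least 2-fold lower, 3 pairs fell together, against a permuted mean of 0.797 (ratio 3.76, permutation p = 0.046). With so few pairs, it cannot be told whether the grouping is particular to rises.

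The median gene span of genes at least 2-fold higher was 2000 bases, against 2105 for other genes and 2319 (2220 to 2430, central 95%) in random sets matched on the mean over all arrays, which itself includes the rise. Matched on the mock mean, the random sets had 2268 (2168 to 2373). In both matchings 0% of 10000 sets lay at or below 2000. The span included introns, and no other property of the genes was tested.

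Of the calls, 66.6% were lower. As a check on RNA degradation, the 3-prime minus 5-prime ranges of 2 of 3 control transcripts overlapped between the groups. That of actin did not overlap. The mean difference, protease IV minus mock, was 0.23 for actin, 0.075 for GAPDH and -0.004 for ubiquitin. Overlap with 3 arrays per group cannot exclude degradation, which stays open. The bacterial controls differed by a median of 0.0747, against -0.0586 for all genes; the bound set for this test took its error over probe sets (0.0145), which leaves out an offset shared by all of an array's probe sets, and the array means overlapped (exact permutation p = 0.3), so an offset cannot be told apart; with arrays centred on these controls 1198 genes were higher and 3501 lower, or 74.5% lower. Centring each array on its median gave 69.3% lower but moved the median difference only from -0.0586 to -0.0743, away from 0, so it does not decide on a uniform shift, which stays open. After cyclic loess 42.4% of calls were lower. That scaling brings the typical difference at each signal level near 0 whatever its cause. It therefore does not decide on a difference between arrays that depends on signal level, which stays open. Dilution by the transcripts that rose was also considered. Probe sets at least 2-fold higher took 13.1% of the summed linear signal in protease IV arrays against 2.63% in mock. This would shift the remainder by -0.164, against a median of -0.148 for genes with a mean of at least 5. As quantile normalization holds each array's total nearly fixed, the -0.164 restates the fall in the remainder's own summed signal. The near match is therefore no separate support for dilution, which stays open. The values also do not show whether such a shift arose in the RNA or in the normalization. A biological fall of many transcripts stays open.

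The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4564 genes, 758 at least 2-fold, and 6 lists; the highest of the other splits gave 0, 0 and 5. For each of these results 1 split, the real one, gave a value as large. Every other split puts mock and protease IV arrays together in a group, so a treatment difference adds to the spread within its groups. The values of the other splits therefore do not measure how many calls chance would give.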
